A study of Mus musculus with 4 samples.

How the data were processed

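RNA was measured by sequencing in 4 mouse libraries from the mesenchyme of molar tooth germs at embryonic day 14. Per the labels, tooth mesenchyme was cut from frozen head sections by laser capture, RNA was prepared with a column kit for very small samples, and cDNA was amplified with the NuGEN Ovation RNA-Seq v2 assay. Laser capture cuts chosen cells from a section with a laser. The amplification copies small amounts of RNA and does not mark strand as far as the labels say, so a gene and its antisense partner were not told apart. The series' design text says that tissue from 3 control and mutant pairs was pooled before RNA extraction. The labels place all libraries in a common sequencing lane and name the strain only as a mixed background. They do not say whether upper and lower molars came from the same embryos.

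Samples were grouped by the labelled genotype and jaw, which gave 4 groups of 1 library each. The labels call the controls Msx1+/-, whereas the series title speaks of wild type. The genotype label Msx1+/- is used here. The labels do not name the Msx1 mutant allele.

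Per the submitters' processing notes, reads were aligned to genome build mm9 with Bowtie 0.12.7 and TopHat 1.4.1. The deposited tables carry the columns of Cufflinks, whose version is not given in the sources used here. Per the file headers, each table holds an FPKM value (fragments per kilobase of transcript, scaled to mapped fragments), a coverage signal and an estimate status for each of 28107 RefSeq transcript entries. Coverage, the mean read depth per transcript base as deposited, equalled FPKM times a constant within each library, so it gave the relative depth of the libraries. The constants were 1.05 for control upper, 0.812 for control lower, 1.09 for mutant upper and 0.924 for mutant lower molar. Whole reads could not be recovered from the FPKM values, so no count model was used and no counting interval is given. The tables held 0 columns with FPKM confidence bounds. An alternative that required bounds of the compared libraries not to overlap had been planned and was not run.

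Transcript FPKM values were summed per gene name, which gave 22072 genes. Genes with a transcript marked as a failed estimate in any library were left out (66 genes), a choice made after the tables were opened. Names of small RNAs (717 names) were left out because FPKM of very short transcripts is unstable. Genes with a mean of at least 1 FPKM over the 4 libraries were kept, which left 10535 genes. Values were converted to log2(FPKM + 1), and every difference is on that scale, which understates the change of weakly expressed genes. FPKM values were used as deposited, with no rescaling, in the main results. Start positions in the tables count from 0, and 1 was added to them. The reference annotation in hand is of build GRCm38, so it was used for gene names and for the GC content of transcripts and never for coordinates.

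With 1 library per group the main results use no test for single genes and give no p-value, and a limma model over all 4 libraries was run as an alternative. A gene was counted as different where the log2 difference was at least 1 in size. Genotype differences are mutant minus control within each jaw, and jaw differences are upper minus lower within each genotype. A gene counted in both jaws had to pass in the same direction in each. The overlap of calls is set beside the number that independent lists would share. A stricter count required the lowest value of one genotype to lie at least 1 above the highest of the other, and the same was done for the jaws and for the diagonal pairing of control upper with mutant lower, which shares no factor.

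Before the data were examined, 28 gene lists were written down, of which 579 of 581 symbols matched the tables. Lists with at least 5 measured members (24 lists) were given the percentile of their median difference among 10000 random lists of the same size, matched on mean level in 20 bins. A list stood apart when its percentile was at or below 2.5 or at or above 97.5, and 1.2 of 24 lists of independently varying genes would do so by chance. Genes of a list can vary together between libraries, so more lists can stand apart without an effect of genotype or jaw. The percentile describes these libraries and is no p-value. The genes named were set by a rule written before the data were examined. It takes Msx1, the 10 largest mean differences each way among genes counted in both jaws, the 5 largest each way counted in 1 jaw alone, the 10 largest jaw differences each way, the 5 largest genotype-by-jaw differences each way, and up to 4 members of each list per contrast. For cell-type lists the 2 most abundant members were added. Genes outside the rule are said to have been chosen after their values were seen. A result that the rule would name is not reported here.

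The alternatives were pseudocounts of 0.1 and 5, no filter on low values, a mean of at least 5 FPKM, rescaling by median of ratios, by a common upper quartile and to a common total, thresholds of 1.5-fold and 4-fold, keeping small-RNA names, and a limma model on log2(FPKM + 1) with genotype and jaw as terms and an adjusted p threshold of 0.05. Keeping genes with a failed estimate and leaving out the mutant lower library were added after the data were seen. The counting rule was checked on simulated data with 10535 genes, of which 100 changed by 1.5 and 100 by 3 on the log2 scale in both jaws, with noise of 0.203 (SD). It counted 89 of the former, 98 of the latter and 0 of 10335 unchanged genes. In the same simulation 1 of 40 random lists stood apart. The noise was drawn alike for every gene and independently between libraries, with no shift of a whole library. The simulation therefore does not give the rate of false counts in the real libraries. For the genotype term limma called 100 of 100 genes at either size and 16 of 10335 unchanged genes. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.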

Results

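Gene expression was measured in the mesenchyme of molar tooth germs from mouse embryos at embryonic day 14. In normal development the tooth epithelium at this age folds into a cap over condensed mesenchyme, the tissue that later forms the dental pulp and dentin. Msx1 encodes a homeodomain transcription factor of the dental mesenchyme, and tooth development in mice that lack it stops at an early stage. The 4 libraries were Msx1+/- (control) and Msx1-/- (mutant) upper molars and control and mutant lower molars, with 1 library in each group. FPKM values in parentheses are given in the order control upper, control lower, mutant upper and mutant lower molar. Summed coverage over annotated transcripts was 410, 324, 395 and 264 megabases in that order. On the usual definition of FPKM, transcripts held 39.2%, 39.9%, 36.3% and 28.6% of mapped sequence. Between 10201 and 10706 genes reached 1 FPKM in a library. No difference below has a replicate check, because no group has a second library, and the jaws may come from the same embryos. A gene is called higher or lower, or counted, only where log2(FPKM + 1) differed by at least 1.

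Msx1 itself (chromosome 5, 38211730 to 38215824, mm9) was still detected in the mutant libraries (170, 184, 126 and 85.9 FPKM). The mutant minus control difference was -0.43 in upper and -1.09 in lower molars, so Msx1 was counted in the lower jaw alone. Relative to the median of all genes these differences were -0.40 and -0.70. The labels do not name the allele and a value per gene does not show which exons were read. The Msx1 level therefore serves as no check of the genotype labels.

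The first comparison asked which genes differed between Msx1-/- and Msx1+/- molar mesenchyme. In both jaws the immediate-early transcription factor genes Egr1, Egr2 and Egr3, which growth factor signals induce within minutes, were far lower in the mutant libraries. Egr3 (chromosome 14, 70477252 to 70479964) had the largest mean difference (113, 60.7, 0.294 and 0.0967 FPKM), at -6.46 in upper and -5.81 in lower molars. Egr1 (chromosome 18, 35020861 to 35024610) differed by -5.60 and -4.94 (167, 113, 2.47 and 2.72 FPKM). The matrix metalloproteinase gene Mmp9 (68.6, 66.4, 1.52 and 0.600 FPKM) and Enpp1, which makes extracellular pyrophosphate (54.8, 50.5, 1.29 and 0.221 FPKM), were lower to a similar degree. The largest mean difference in the other direction was in Lrrtm1 (chromosome 6, 77192711 to 77195511), which encodes a synaptic adhesion protein (2.71, 8.06, 38.8 and 75.1 FPKM). The collagen gene Col8a1 (chromosome 16, 57624369 to 57754850) was next, at 3.46 and 2.61 (3.53, 5.98, 48.9 and 41.5 FPKM).

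Counted in both jaws were 210 genes, of which 42 were higher and 168 lower in the mutant. In upper molars 113 genes were higher and 343 lower, and in lower molars 91 were higher and 994 lower. Independent lists of these sizes would share 0.976 higher and 32.4 lower genes. The median difference of all genes was -0.03 in upper and -0.39 in lower molars, so the mutant lower library was lower over most genes. After rescaling by median of ratios, 65 genes were higher and 128 lower in both jaws, and 41 of the 42 higher and 128 of the 168 lower genes were shared with the calls on deposited values. In lower molars rescaling gave 208 higher and 371 lower genes. With the stricter rule of full separation 27 genes were higher and 125 lower between the genotypes, against 6 and 2 between the jaws and 3 and 0 for the diagonal pairing. Rescaled, the same rule gave 40 higher and 103 lower genes between the genotypes and 4 and 4 between the jaws. Across genes, the genotype differences of the jaws correlated with a Pearson r of 0.531 and a Spearman rho of 0.442, where genes are not independent replicates.

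**Figure D1:**
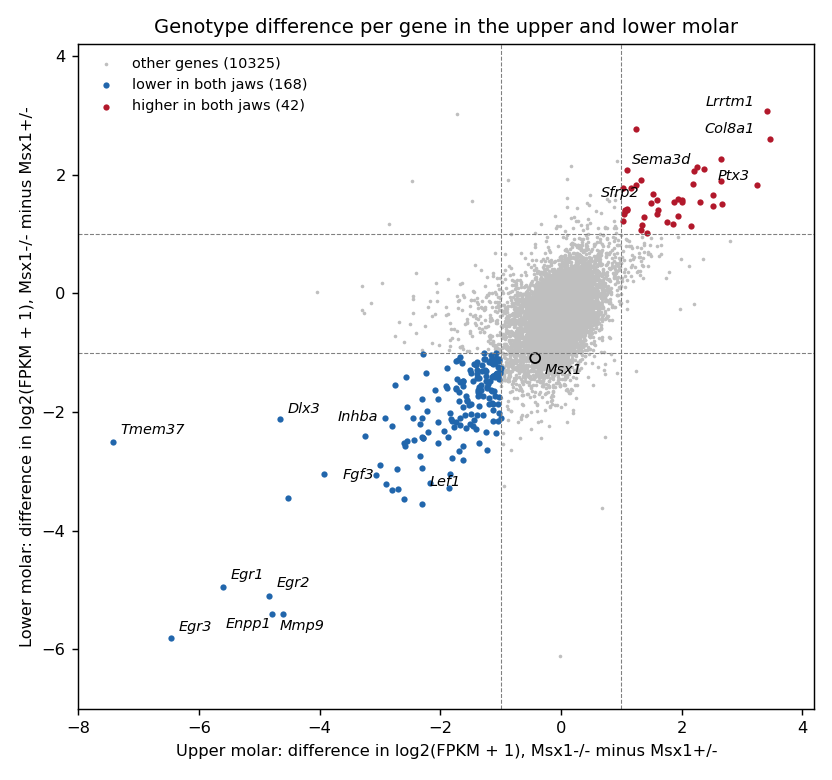
Difference in log2(FPKM + 1), mutant minus control, of 10535 genes in upper molars (horizontal axis) and lower molars (vertical axis). Each point is a gene, dashed lines mark a difference of 1 in size, blue points are the 168 genes lower and red points the 42 genes higher in both jaws, and the open circle marks Msx1 at -0.43 and -1.09.

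Among the other genes with the largest mean differences, Ptx3 (0.684, 0.747, 15.0 and 5.16 FPKM), Ncam2 (0.527, 0.893, 8.60 and 8.13 FPKM), Nxph1 (0.436, 2.13, 7.99 and 10.6 FPKM) and Sema3d (0.678, 1.27, 7.64 and 8.67 FPKM) were higher in the mutant. Odz2, Zcchc5, Cntn6 and the collagen cross-linking enzyme gene Lox completed the 10 highest, with Lox at 2.05, 3.78, 18.4 and 12.6 FPKM. On the lower side stood Egr2 (32.0, 34.1, 0.156 and 0.0260 FPKM), Nptx1 (27.3, 12.2, 0.221 and 0.207 FPKM), Mical2 (9.97, 10.8, 0.311 and 0.414 FPKM) and Dlx1as (98.9, 59.9, 5.52 and 6.42 FPKM). Dlx1as lies antisense to Dlx1, and the libraries are not known to keep strand. Tmem37 (296, 7.86, 0.738 and 0.569 FPKM) and the homeobox gene Dlx3 (55.6, 11.9, 1.25 and 1.97 FPKM) were also among the 10 lowest. Both belonged to 24 genes that were at least 4-fold higher in the control upper library than in every other library.

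Genes of Fgf signalling were lower as a group. The Fgf list (21 measured genes) had a median difference of -0.56, below each of 10000 matched random lists, and 6 of its genes were lower and 0 higher in both jaws. They were the ligand gene Fgf3 (6.44, 8.66, 0 and 0.0365 FPKM), the feedback inhibitor genes Spry4 (18.7, 19.8, 2.88 and 3.52 FPKM), Spry1 and Dusp6, and the target transcription factor genes Etv4 (6.69, 4.13, 0.315 and 0.360 FPKM) and Etv5 (21.6, 16.4, 3.82 and 3.42 FPKM). Spry1 was not counted after any of the 3 rescalings and Dusp6 was not after rescaling to a common upper quartile. The 15 members not counted, a remainder set by the change itself, stood at percentile 1.99 in upper and 91.6 in lower molars. Fgf10 among them, chosen after its values were seen, was at 1.74, 2.12, 3.66 and 8.34 FPKM. The list of immediate-early and stress genes (17 measured) had a median of -0.63, also below each random list, with Egr1, Egr2, Egr3, Ier2 and Fosl2 lower. Ier2 was at 12.8, 12.1, 3.32 and 3.64 FPKM. Fosl2 (15.4, 10.1, 6.66 and 4.15 FPKM) was not counted after any of the 3 rescalings.

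Wnt ligands and targets (20 measured) had a median difference of -0.55, below each random list, with 4 genes lower and 0 higher. The nuclear Wnt effector gene Lef1 was at 117, 93.5, 23.1 and 11.3 FPKM, and Lgr6 was at 10.7, 3.83, 1.13 and 0.121 FPKM. Sp5 and Wnt9a were the other counted members, and Wnt9a was not counted after rescaling by median of ratios or to a common upper quartile. With no filter on low values this list stood at percentile 29.1. Wnt antagonists (12 measured) did not stand apart (percentile 64.7). Within that list the secreted antagonist Sfrp2 was higher (111, 124, 316 and 359 FPKM), whereas Wif1 (7.21, 11.1, 2.59 and 2.31 FPKM) and Shisa2 (14.4, 13.5, 6.06 and 2.26 FPKM) were lower. Dkk2 (4.55, 10.3, 16.5 and 20.6 FPKM) differed by 1.66 in upper and 0.94 in lower molars and was counted in both jaws after rescaling by median of ratios.

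The Bmp list (24 measured) had a median of -0.34 at percentile 7.72, and Bmp3 alone was lower in both jaws (12.4, 8.44, 1.20 and 0.647 FPKM). By jaw the list stood at percentile 1.06 in upper and 3.86 in lower molars. With a mean of at least 5 FPKM it stood apart in the mean difference (percentile 0.275). The Bmp target genes Id1 (21.8, 23.8, 12.3 and 8.17 FPKM) and Id3 (115, 96.0, 66.9 and 43.7 FPKM) were not counted in both jaws. Bmp4, chosen after its values were seen, was at 25, 34.7, 17.6 and 20.2 FPKM. The activin and Tgf-beta list (17 measured) had a median of -0.03 at percentile 98.7, above most random lists. Its 2 counted members went the other way, with the activin subunit gene Inhba at 174, 138, 23.9 and 28.5 FPKM and Tgfb1 at 12.4, 9.14, 3.17 and 2.19 FPKM. That list stood at percentile 93.7 with no filter and 86.9 with a mean of at least 5 FPKM.

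The Notch list (13 measured) had a median of -0.42 at percentile 2.40, with 4 genes lower. Its counted members were the target genes Hey1 (26.4, 32.8, 6.64 and 3.07 FPKM), Hes1 (14.7, 18.5, 5.61 and 2.88 FPKM) and Heyl, and the receptor gene Notch1. With a mean of at least 5 FPKM the Notch list stood at percentile 5.83, with a pseudocount of 5 at 3.585 and without a filter at 2.91. It did not stand apart in these settings. With a pseudocount of 5, Hes1, Heyl and Notch1 were no longer counted. By jaw the list stood at percentile 0.18 in upper and 2.695 in lower molars. The retinoic acid list (11 measured) had a median of -0.60 at percentile 0.285. Without a filter it stood at percentile 3.42. By jaw it stood apart in lower molars (median -0.90, percentile 0.285) but not in upper molars (median -0.24, percentile 5.6). The hedgehog list (11 measured) stood at percentile 6.67 with 0 genes counted in both jaws, and Gli3 was at 27.6, 21.5, 15.4 and 10.3 FPKM. By jaw that list stood at percentile 91.8 in upper molars and 1.85 in lower molars, where 4 genes were lower.

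Among transcription factors of the dental mesenchyme (21 measured, percentile 19.2), 3 genes were lower and 1 was higher. Dlx2 (56.3, 34.7, 14.7 and 2.66 FPKM), Runx2, which is required for bone and tooth mineral tissue (70.7, 52.0, 26.4 and 11.8 FPKM), and Prrx2 (83.9, 73.7, 26.6 and 25.8 FPKM) were the lower genes, of which Prrx2 was not counted after rescaling to a common upper quartile. Osr1 was higher (4.70, 12.2, 13.3 and 26.5 FPKM). Pax9, chosen after its values were seen, was at 45.7, 46.3, 68.1 and 66.1 FPKM and was not counted.

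**Figure D2:**
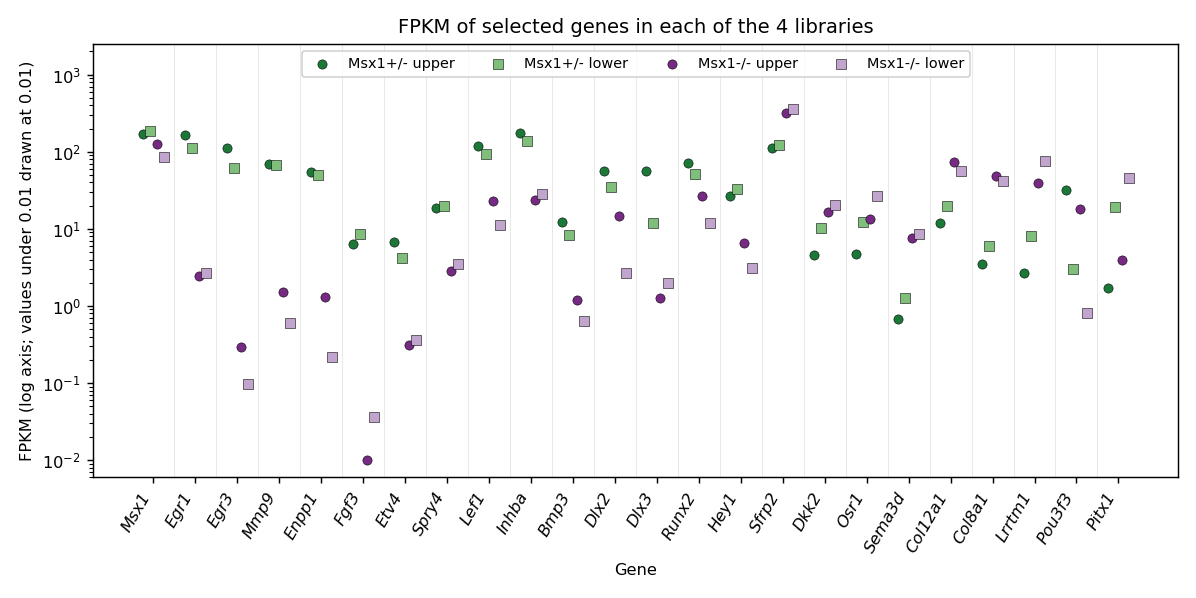
FPKM (log axis) of 24 genes in the 4 libraries, with circles for upper and squares for lower molars, green for control and purple for mutant. Each point is 1 library and values under 0.01 are drawn at 0.01. Egr1 lies at 167 and 113 FPKM in the control and at 2.47 and 2.72 FPKM in the mutant libraries.

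Cell cycle genes (36 measured) stood at percentile 95.1 with 0 genes counted, and Pcna was at 67.3, 81.8, 43.2 and 34.7 FPKM. With a mean of at least 5 FPKM that list stood at percentile 98. Among CDK inhibitors and D cyclins (8 measured, percentile 59.3), the inhibitor gene Cdkn1a (5.86, 7.91, 0.493 and 0.763 FPKM) and the cyclin gene Ccnd2 (136, 105, 41.2 and 29.1 FPKM) were both lower. Extracellular matrix genes and syndecans (40 measured) had a median of -0.14 at percentile 99.6, which is 0.08 above the median of all genes. In that list the collagen gene Col12a1 was higher (12, 19.7, 73.3 and 56.1 FPKM), and Timp1 (27.8, 38.8, 3.14 and 3.00 FPKM), Sdc4 and Timp3 were lower. Timp3 was not counted after any of the 3 rescalings. Guidance and neurotrophic ligands (22 measured) had a median of -0.01 at percentile 99.9, with Sema3d and Epha3 higher (19.1, 15.3, 52.8 and 31.8 FPKM for Epha3) and Unc5b and Efnb2 lower (20.5, 13.4, 3.38 and 2.37 FPKM for Unc5b). Housekeeping genes (15 measured) stood at percentile 6.75 with 0 counted, and Actb was at 1151, 1086, 946 and 490.5 FPKM. With a pseudocount of 5 that list stood at percentile 2.35.

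Osteoblast markers (8 measured) did not stand apart (percentile 97.2). They did with a pseudocount of 5 (98.46), a mean of at least 5 FPKM (98.765) and rescaling by median of ratios (97.54). Their counted members went both ways, with the bone matrix genes Ibsp (4.25, 2.40, 19.1 and 9.21 FPKM) and Ifitm5 higher and Spp1, another bone matrix gene, lower (5.70, 6.92, 0.0217 and 0.0213 FPKM). Cartilage markers (5 measured) had a median of 0.61 at percentile 99.98, with Hapln1 higher (1.30, 1.70, 3.93 and 10.3 FPKM) and Col2a1 at 2.03, 1.98, 4.59 and 7.20 FPKM. Markers of epithelium, which laser capture was meant to leave out, had a median of 0.35 (10 measured), above each random list. Krt15 was counted (0.865, 1.94, 3.15 and 9.09 FPKM), and the most abundant of that list were Krt5 (7.18, 17, 21.3 and 28.1 FPKM) and Krt14 (8.69, 14.8, 13.3 and 14.5 FPKM). Macrophage markers (13 measured) had a median of 0.19 at percentile 99.96 with 0 counted, and C1qc was at 3.60, 6.56, 7.22 and 11.6 FPKM.

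Markers of other cells did not stand apart in the mean genotype difference over the jaws. In upper molars alone erythroid markers stood at percentile 0.22 and pericyte markers at 0.30, against 30.6 and 54.8 in lower molars. In the mean difference, erythroid markers stood apart when rescaled to a common total (2.31) and pericyte markers with a pseudocount of 5 (1.12). Erythroid markers (8 measured) stood at percentile 4.49, with embryonic globin Hbb-y at 360, 466, 257 and 322 FPKM. Reads of globin genes can be shared between near-identical copies. Endothelial markers (18 measured) stood at percentile 21.1, with Cdh5 at 18.9, 18.1, 16.5 and 17.4 FPKM. Pericyte and smooth muscle markers (5 measured) stood at percentile 3.67, with Rgs5 at 11.8, 10.8, 5.96 and 2.07 FPKM. Of the hypoxia and glycolysis genes (19 measured, percentile 6.02), Vegfa was lower (11.9, 8.84, 4.93 and 2.74 FPKM), but not after rescaling to a common upper quartile. That list stood apart with a pseudocount of 0.1 (2.11) and a mean of at least 5 FPKM (1.785). It also did when rescaled to a common upper quartile (2.22) or a common total (1.93). Of the glia and neuron list only Nefl (0.658, 0.829, 0.550 and 3.52 FPKM) and Gap43 were measured, and of the skeletal muscle list only Chrna1 (2.70, 2.43, 1.90 and 1.52 FPKM) and Tnnt1. The sex-linked genes Xist (27.8, 27.7, 27.0 and 29.0 FPKM) and Ddx3y (2.15, 2.60, 2.24 and 1.26 FPKM) were both detected in every library.

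**Figure D3:**
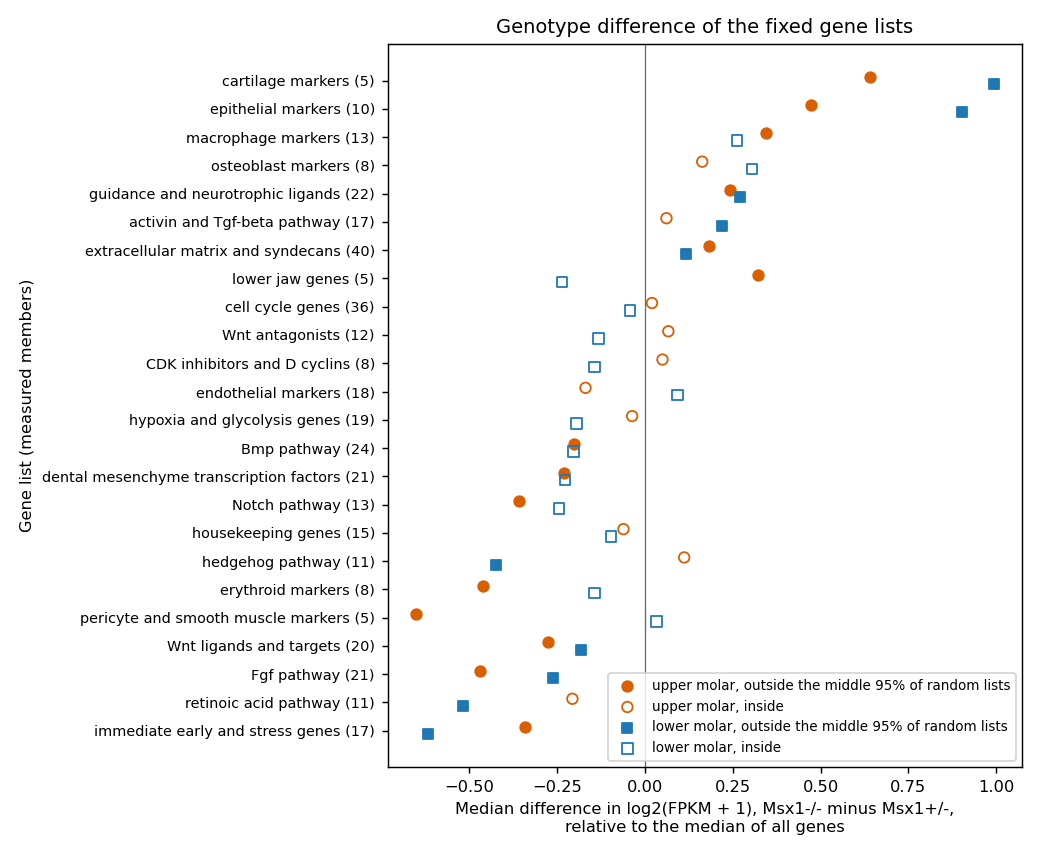
Median difference in log2(FPKM + 1), mutant minus control, of the 24 gene lists with at least 5 measured members, relative to the median of all genes. Circles are upper and squares lower molars, and filled symbols mark lists that stood apart from 10000 matched random lists. Lists are ordered by the median of the mean difference over the jaws, with cartilage markers at the top and immediate-early and stress genes at the bottom.

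Some genotype differences were counted in 1 jaw alone, and whether they differ between jaws was not tested. In upper molars Tbx15 (1.70, 4.74, 17.9 and 9.52 FPKM), Cbln2, the smooth muscle actin gene Acta2 (2.53, 4.18, 15.2 and 3.57 FPKM), Gdf10 and Pcdh10 were higher in the mutant. Cytip (16.1, 0.0280, 0.0336 and 0.0440 FPKM), 6030405A18Rik, Slc25a42, Mamld1 and Adcy4 were lower there, and all 5 were among the 24 genes high in the control upper library alone. In lower molars Akr1b3, Perp, Pisd-ps3, the growth factor gene Igf1 (10.1, 3.04, 10.9 and 14.4 FPKM) and Fam166a were higher in the mutant. Of these, Akr1b3 passed the rule in both jaws in opposite directions, at -1.72 in upper and 3.02 in lower molars. Gm9846, the neuropeptide gene Calca (25, 23.9, 40.9 and 1.04 FPKM), the retinoic acid synthesis gene Aldh1a2 (21.1, 12.3, 10.5 and 0.397 FPKM), Vgll4 and Sfrp4 were lower there. Gm9846 was seen in control lower molars alone (0.0223, 68.2, 0.0122 and 0.00438 FPKM). Rescaling changed some of these calls. Tbx15 was counted in both jaws under all 3 rescalings, and Pcdh10 under a common upper quartile and a common total. With a common total, Cbln2, Gdf10, 6030405A18Rik, Perp and Sfrp4 were also counted in both jaws. The genotype difference itself differed between jaws by at least 1 in 728 genes, of which 590 were more positive and 138 more negative in upper molars. Rescaled by median of ratios, 449 genes did, 168 more positive and 281 more negative. The largest positive values were in Gm9846, Calca, Terc, Gria2 and Acta2 and the largest negative in Tmem37, Akr1b3, Rangrf, Cytip and Fxyd3.

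The other comparison was between upper and lower molars of the same genotype. The homeobox gene Pitx1, a known determinant of mandibular identity (chromosome 13, 55926415 to 55932786), was higher in lower molars of either genotype (1.72, 19.0, 3.98 and 45.8 FPKM). The POU-domain gene Pou3f3, known from the maxillary arch (chromosome 1, 42753991 to 42757054), was higher in upper molars (32.3, 3.03, 17.9 and 0.808 FPKM). These markers run with the jaw labels in all 4 libraries. In both genotypes 14 genes were higher in upper and 3 in lower molars, where independent lists would share 5.02 and 0.0939. Calls in opposite directions also overlapped more than independent lists would, with 3 genes against 0.637 and 3 against 0.740. The excess over independent lists alone therefore does not show a jaw difference shared by the genotypes. Control libraries gave 156 genes higher in upper and 23 in lower molars, and mutant libraries 339 and 43. Rescaled by median of ratios, the mutant libraries gave 147 and 92, and 14 and 8 genes were counted in both genotypes, of which 10 and 3 were shared with the calls on deposited values. Across genes the jaw differences of the genotypes had a Pearson r of 0.147 and a Spearman rho of 0.131. The control jaw difference followed transcript length across genes (Spearman rho 0.356).

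The genes higher in lower molars in both genotypes were Pitx1, Lrrn1 (1.83, 7.34, 1.84 and 11.4 FPKM) and Gsc (0.660, 4.59, 2.06 and 7.13 FPKM). Higher in upper molars were, after Pou3f3, the transcripts 2900092D14Rik (11.6, 1.01, 6.79 and 0.166 FPKM) and 2610017I09Rik (16.9, 3.28, 16.8 and 2.24 FPKM), Pla2g7 (15.1, 3.92, 5.60 and 0.184 FPKM), Arhgap10, Klhl34, Gm12191, the growth cone gene Gap43 (9.0, 3.54, 18.5 and 3.91 FPKM), Hist2h4 and Mkx. Hist2h4 and Gm12191 have near-identical copies that can share reads, and Arhgap10 is among the genes high in control upper molars. The fixed list of lower jaw genes (5 measured) had a median of -1.40, below each random list, with Dlx5 at 6.64, 28.0, 7.44 and 14.6 FPKM and Dlx6 at 0.691, 4.55, 1.07 and 2.60 FPKM. Its member Dlx3 went the other way in the control libraries (55.6, 11.9, 1.25 and 1.97 FPKM). Between genotypes the same list stood at percentile 65.9. Of the upper jaw list only Pou3f3 and Irx5 (0.951, 0.763, 2.90 and 0.744 FPKM) were measured.

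Of the 24 lists 10 stood apart in the mean jaw difference over the genotypes. The lower jaw list and epithelial and macrophage markers were below each random list, and stood apart toward lower molars in control and in mutant libraries taken alone. Extracellular matrix genes (percentile 0.140) stood at 0.0700 in control and 3.38 in mutant libraries, and dental mesenchyme transcription factors (99.96) at 99.99 and 95.8. The other 5 lists stood apart in the mutant libraries but not in the control libraries, a contrast that was not tested. Fgf genes (percentile 0.01) stood at 90.8 in control and 0.0300 in mutant libraries and erythroid markers (0.0300) at 13 and 0.110. Toward upper molars, Bmp genes (99.87) stood at 58.1 and 99.7, hedgehog genes (99.97) at 81.1 and 99.4, and hypoxia and glycolysis genes (98.8) at 52.3 and 99.9. The mutant jaw difference includes the mutant lower library, in which transcripts held 28.6% of mapped sequence. With a mean of at least 5 FPKM the Bmp list stood at percentile 85.5 and the hypoxia list at 95.1. Single members were rarely counted in both genotypes. Among these 10 lists only Pitx1 and Gsc were. The hedgehog receptor gene Ptch1 was at 18.4, 15.4, 20.9 and 6.66 FPKM.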

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

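Of the tests in this part, those of stress, library scaling, dental mesenchyme share, Fgf response, GC content and length, amplification and jaw-linked genes were chosen only after the result was seen, and the test of a common factor in the mutant lower library was chosen before. A first test of library scaling asked how many of the 9 Egr and Fgf-list genes stayed counted, found 8, 7 and 8 under the 3 rescalings, and missed the bound of at least 8 set for it. A second used the median of the 9 genes relative to all genes, -1.97 in the jaw where it was smaller, which their selection as lower genes largely fixes, so whole fixed lists were used here. A first test of the Fgf response used the whole list, whose higher percentile of the jaws was 0.40, and was replaced because the pattern's own genes are in that list, which turned its reading from for a lower response to open. The replacement takes out the genes counted as lower, which raises the percentile by construction, so neither test decides. A first test of jaw-linked genes took the 24 genes themselves (median 0.17), which had been selected as low in mutant upper molars, and was replaced by genes selected on the control libraries alone. The bound of the stress test was made stricter after the percentile of the list without the Egr genes was seen, which turned its reading from against stress to open.

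The first pattern is the low level of Egr1, Egr2, Egr3 and 6 Fgf-list genes in both mutant libraries. Library scaling is argued against as the whole cause, because a factor moves random lists alike, and the whole Fgf list and the immediate-early and stress list stood at percentile 0.40 or lower in each jaw. A lower share of dental mesenchyme in the mutant captures stays open. The fixed list of dental transcription factors had a median of -0.14 relative to all genes (interquartile range 1.18), against -2.05 for the 9 genes. The list as a whole did not fall by a like amount. The 9 genes were selected as lower, which largely fixes that gap, so it cannot decide. That list stood at percentile 1.49 in upper and 16.0 in lower molars. Other markers went both ways (epithelial 0.57, macrophage 0.41, cartilage 0.83, erythroid -0.26 and pericyte -0.30 relative to all genes). Handling stress in the control libraries may contribute and stays open, since 14 stress genes other than the Egr genes had a median of -0.39 (interquartile range 0.675) against -5.05 for the Egr genes, yet stood at percentile 0.0200 of random lists. A lower Fgf response in Msx1-/- mesenchyme, a biological explanation, stays open too. The 15 Fgf-list genes not counted stood at percentile 1.99 in upper and 91.6 in lower molars. Taking out the genes counted as lower raises that percentile by construction, so it cannot decide. The whole list stood at percentile 0.40 or lower in each jaw but holds the pattern's own genes.

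The second pattern is the lower level of most genes in the mutant lower library, where the median of all genes was -0.39 and transcripts held 28.6% of mapped sequence against 39.9% in control lower molars, a log2 ratio of -0.48 beside a median log2 ratio of FPKM, with no pseudocount, of -0.48. GC content or transcript length is argued against as the whole cause, since the lower-jaw difference had a Spearman rho of 0.0512 with GC content (90.7% of genes had a value) and 0.0878 with length. A common factor for the library cannot be told apart from a change that depends on level. The median log2 ratio differed by 0.24 between the highest and lowest of 5 equal groups of genes by level (95% bootstrap interval 0.20 to 0.29, 1000 draws), between the bounds of 0.1 and 0.3 set beforehand, and by 0.18 in upper molars. A genotype effect that holds for lower molars remains untested with 1 library.

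The third pattern is the set of 24 genes at least 4-fold higher in the control upper library than in every other, among them Tmem37, Cytip, Lsm2 (242, 58.4, 44.7 and 36.5 FPKM) and Tmem9 (168, 33.2, 25.3 and 23.5 FPKM). The other libraries had 1, 0 and 0 such genes. A jaw difference shared by both genotypes is argued against for most of them, since 34 genes were at least 4-fold higher in control upper than control lower molars, these 24 included, and their median difference in the mutant libraries was 0.18 (interquartile range 0.71) against 0.27 for all genes, with 5 of 34 at 1 or more. Uneven amplification or a mapping error in that library may account for them and cannot be told apart from a control upper molar programme that needs Msx1, because the group has no second library.

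Some genes went opposite ways between the jaws or the genotypes, each by at least 1, and none of these differences was tested because no group has a second library. The genotype difference in upper minus lower molars was -4.75 for Akr1b3, -4.01 for Fxyd3, -3.02 for Gdf7, 2.55 for Gria2 and -4.37 for Rangrf. Akr1b3 was at 12, 0.000260, 2.92 and 7.13 FPKM and Rangrf at 4.53, 0.000203, 0.000237 and 2.73 FPKM in the order used above. Gdf7 was at 11.1, 1.84, 3.37 and 7.34 FPKM. The jaw difference in control minus mutant was 4.75 for Akr1b3, -2.16 for Crabp1 (24.2, 55.1, 27.8 and 13.3 FPKM), 4.01 for Fxyd3, -2.27 for Gm4535, 4.37 for Rangrf and -3.15 for Terc.

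Among the small-RNA names left out of the comparisons, 5 microRNA genes were listed at 0 in both control libraries and above the size rule in both mutant libraries. The mean FPKM of the mutant libraries was 2.32 for Mir181b-2, 2.73 for Mir377, 2.22 for Mir490, 2.54 for Mir665 and 2.91 for Mir668. Lower in both mutant libraries were Mir1893 (6.58, 8.0, 2.15 and 2.53 FPKM), Mir1907 (3.39, 5.08, 1.07 and 1.18 FPKM), Snora52 (4.67, 5.10, 1.24 and 0.667 FPKM) and Snord12 (5.11, 13.5, 0 and 0 FPKM). FPKM of such short genes rests on few reads, and a value listed at 0 can be a failed estimate. Mir377, Mir665 and Mir668 lie on chromosome 12 between positions 110824524 and 110978787 (mm9). The imprinted transcripts Meg3 (8.83, 9.09, 12.5 and 27.2 FPKM) and Rian (17.2, 19.3, 25.2 and 22.4 FPKM) are known from that region.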

How the results depend on the processing

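The tests that keep genes with a failed estimate, that leave out the mutant lower library, and that recompute single genes under other scalings and pseudocounts were chosen only after the data were seen. Under the alternatives run for them, none of the 207 recomputed genes, the lists that stood apart or the correlations reversed. The split of the genotype-by-jaw calls turned from 590 positive and 138 negative to 168 and 281 after rescaling by median of ratios. It also turned with a common upper quartile (170 and 283), a common total (330 and 455) and a 4-fold threshold (17 and 23). The diagonal split turned from 3 and 0 to 5 and 7 with a 1.5-fold threshold. Of 134 recomputed summary values 71 lay close to the main value and 63 moved, and the cause was not tested beyond what a stricter or looser rule does by construction. Counts are given in the order genotype in upper molars, in lower molars and in both jaws, jaw in control, in mutant and in both genotypes, full separation by genotype, by jaw and on the diagonal, and genotype by jaw. The main counts were 456, 1085, 210, 179, 382, 17, 152, 8, 3 and 728. A 1.5-fold threshold gave 1385, 3641, 739, 717, 2005, 140, 466, 30, 12 and 3281, and a 4-fold threshold 92, 101, 42, 36, 20, 4, 31, 3, 0 and 40. A pseudocount of 0.1 gave 741, 1883, 367, 320, 876, 62, 235, 20, 5 and 1544, and a pseudocount of 5 gave 180, 349, 80, 68, 100, 6, 61, 3, 0 and 190. With a mean of at least 5 FPKM, where fewer genes enter, the genotype counts were 265 in upper molars, 130 in both jaws and 96 with full separation, the jaw counts 101 in control and 5 with full separation, and genotype by jaw 479. Rescaling by median of ratios moved lower molars to 579, jaw in mutant to 239 and genotype by jaw to 449, and a common upper quartile moved them to 569, 240 and 453. Rescaling to a common total, which raises FPKM against the pseudocount, gave 694 in upper molars, 326 in both jaws, 338 for jaw in control, 49 in both genotypes, 18 for jaw separation and 6 on the diagonal. Keeping small-RNA names gave 9 on the diagonal. Without the mutant lower library only 1 jaw or genotype remains, with 456 genes by genotype and 179 by jaw.

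The limma model with genotype and jaw as terms called 680 genes by genotype (113 higher, 567 lower) and 98 by jaw (81 higher in upper, 17 in lower molars) at an adjusted p threshold of 0.05. Its estimated prior gave every gene the same standard error (0.297), so these calls act as a threshold on the fold. It has 1 residual degree of freedom and takes the jaws as independent samples, so its p-values are too small if the jaws share embryos. The jaw term compares the genotypes within each jaw. No pairing by embryo was possible because the labels give no replicate numbers and each group has 1 library. The planned rule on FPKM confidence bounds was not run, as the tables held 0 such columns.

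The correlation of genotype differences between the jaws ranged from 0.493 with small-RNA names kept to 0.546 when rescaled to a common total. The mean Msx1 difference ranged from -0.77 to -0.45 and Msx1 was not counted in both jaws under any scaling or pseudocount run. The number of lists apart by genotype was 11 and ranged from 9 to 13. Of 326 recomputed list percentiles 302 kept their side of the bounds, 15 came to stand apart and 9 no longer did. Dental mesenchyme transcription factors moved from percentile 19.2 to stand apart on the high side without a filter (98.9). Of 1035 recomputed single-gene calls over 207 genes, 953 kept their side, 36 came to be counted and 46 no longer were, 28 of them with a pseudocount of 5. Depth limits what is said of genes near 1 FPKM, since whole reads could not be recovered and the mutant lower library held 264 megabases of transcript coverage against 410 in control upper.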

Other observations

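The genes in this part were chosen after their values were seen, and its test was chosen only after the result was seen. Some genes known from nerve cells were counted in both jaws, in either direction, and no list or enrichment was tested for them. Pcdh9 (1.05, 0.690, 3.87 and 10.6 FPKM), Flrt2 (6.33, 6.80, 21.1 and 22.1 FPKM), Cntn3 (1.01, 1.19, 3.22 and 4.77 FPKM), Lrrc4c (0.409, 0.362, 1.85 and 3.66 FPKM) and the neurotrophin receptor gene Ntrk2 (2.89, 2.60, 14.0 and 7.88 FPKM) were higher in the mutant. The pentraxin gene Nptx2 (2.82, 4.15, 0.278 and 0.0663 FPKM), Syn1 (10.2, 5.17, 0.177 and 0.163 FPKM), the activity-regulated gene Arc (2.85, 2.47, 0.146 and 0.131 FPKM) and the opioid precursor gene Penk (99.0, 108, 17.6 and 18.6 FPKM) were lower.

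Nab2, a corepressor that Egr proteins are known to induce, was lower in the mutant (67.5, 42.3, 12.9 and 11.6 FPKM), as were the growth factor response genes Klf10 (17.6, 16.8, 1.86 and 0.814 FPKM) and Errfi1 (13.2, 14.7, 3.16 and 2.29 FPKM). The metallothionein genes Mt1 (21.0, 27.8, 2.26 and 8.90 FPKM) and Mt2 (14.2, 27.0, 0.890 and 2.77 FPKM), which bind zinc and other metals, were lower too, and their reads can be shared between near-identical copies. Fos, a stress-induced immediate-early gene, was low in all libraries (1.12, 0.959, 0.206 and 0.143 FPKM). The Igf-binding protein genes Igfbp3 (43.2, 92.0, 18.9 and 28.6 FPKM) and Igfbp7 (18.2, 26.4, 4.72 and 8.02 FPKM) were lower in both jaws.

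A hypothesis for part of the genotype differences is strain-linked sequence around the Msx1 locus, since the strain is labelled as mixed and DNA near a mutated gene is inherited with it. Within 10 Mb of Msx1, 4 of 106 measured genes were counted in both jaws, where 2.11 would be at the rate of all genes. The 4 genes were Stk32b (9.35, 9.03, 1.53 and 0.737 FPKM), Htra3 (3.99, 5.46, 0.565 and 0.510 FPKM), Fosl2 and Sorcs2 (1.36, 0.516, 6.12 and 2.84 FPKM). The excess is too small for so few genes to decide, so an effect of linked sequence may be present and cannot be told apart from chance here.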
